A study of Mus musculus with 16 samples.

How the data were processed

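The labels describe female mice of C57BL/6 background and donor T cells recovered after syngeneic or allogeneic haematopoietic stem cell transplantation, from spleen and, after allogeneic transplantation, from ovary. CD4+ and CD8+ cells were sorted in 2 rounds, their RNA was extracted with Trizol and labelled with Cy3 by the Low Input Quick Amp kit, per the labels' protocols. There were 16 arrays in 6 groups: ovarian CD8 (4), allogeneic splenic CD8 (3), syngeneic splenic CD8 (3), and 2 each of ovarian CD4, allogeneic splenic CD4 and syngeneic splenic CD4. The arrays lie on 2 slides with every group on both, and were scanned on 1 date.

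The deposited scanner tables hold the intensity of each spot in arbitrary units, background-subtracted and detrended by Agilent Feature Extraction 11.5.1.1, per the file headers. The processed signal and the calls of spots well above background, saturated or non-uniform were read from them. The mean signal column was absent from the tables read here, so the median signal and median local background were used where raw intensities were needed. The deposited series matrix holds log2 values. That each is an array's log2 processed signal minus its 75th percentile, then minus the probe's median over the arrays, was found from the values: Pearson r with values so computed was at least 0.9998 on every array, and array medians ran from -0.344 to 0.494. The software the authors used for that normalization is not given in the sources used here.

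Each array's log2 processed signal was shifted by its 75th percentile. Saturated spots numbered 0 on every array. Of 55681 probes, 27656 were named by matching their accessions to a RefSeq gene table (assembly GRCm38.p6), giving 20972 symbols, and 28025 stayed unnamed. Positions are not given because the array's coordinates use another build. The integrin gene Itgae, meant to be among the T-cell genes given in any case, had no named probe and was not analysed here. Probes were kept if well above background on every array of at least 1 of the 6 groups (31116 probes), and the probe with the highest mean over the 16 arrays stood for its gene. That left 22831 features, 13696 with a symbol. Among called genes recomputed under every alternative, 40 pairs of a gene and a comparison had a further probe, and 0 of them a further probe in the opposite direction.

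A limma model with 1 mean per group was fitted to all 16 arrays (10 residual degrees of freedom, 2.16 from the prior), and a feature was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were ovary against spleen and allogeneic against syngeneic in each subset, ovarian CD8 against CD4, and the interactions of subset with tissue and with transplant. Overlaps of calls were tested with Fisher's exact test. In the comparisons of 2 groups, 34 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 5 measured genes. The list tests left out 239 genes with a missing value. Counts of measured and called members include such genes, Gzmb and Birc5 among them, so they can cover more genes than the list's p. The lists cover T-cell effector, cytokine, chemokine, residency, homing, naive, inhibitory, costimulation, regulatory and helper genes, cell cycle, interferon responses, metabolism, stress, ribosomal proteins, and other cell types of ovary and spleen. The list a gene belongs to was fixed beforehand, and some genes stand in more than 1 list.

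Comparisons, tests, lists and most alternatives were set before the data were examined. So was the rule for genes to be named: in the main comparisons, among called symbols with separated arrays and a higher group well above background, the 10 largest rises and falls; up to 4 members of each list with the smallest p; 22 T-cell genes, of which the text gives 21, and 4 sort markers in any case; and the 5 largest of each direction in ovarian CD8 against CD4 and in the interactions. That rule met 818 pairs of a gene and a comparison. The 230 pairs recomputed under every alternative are a part of them, picked after values and, for some, their stability had been seen. Counts of stable values over those pairs are therefore not those of the whole rule.

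Alternatives were quantile normalization; normexp background correction with an offset of 50 followed by quantile normalization; the series matrix; no filter, or a filter on all 16 arrays; the mean of a gene's probes; the slide as a block, and each slide alone; the replicate number as a block; array weights; a trended robust variance; fitting only the groups compared; a 2-fold threshold; leaving out each array; and, for lists, a correlation estimated per list and the rotation test fry. Added after the data had been seen were a filter on the groups compared, a common signal floor of -2.50, leaving out the 2 dimmest arrays, features with a symbol only, and each slide alone for lists. With 1 array left in a group, that array was assumed to vary like the others.

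The model was tested on simulated data of 22592 genes with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 40% and 79% at the sizes of the CD8 ovary comparison (4 false calls), 26% and 67% for CD4 ovary (6), 23% and 71% for the CD8 transplant comparison (6) and 9% and 77% for the CD4 transplant comparison (5). A shifted list was called in all 4 simulations and 0 of the other lists. Simulated genes varied independently of each other, unlike the genes of many real lists. The simulations therefore cannot show how often correlated genes lead to false list calls. Each simulated gene also had the same spread in every group, which is what the fit assumes. False calls that arise where groups differ in spread were therefore not tested. Work used R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.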

Results

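Donor T cells were profiled on 16 one-colour expression arrays in a mouse model of graft-versus-host disease of the ovary, in which T cells of an allogeneic graft attack the recipient's organ. CD8+ cells came from the spleen after syngeneic transplantation (3 arrays), from the spleen after allogeneic transplantation (3 arrays) and from the ovary after allogeneic transplantation (4 arrays). CD4+ cells came from the same 3 sources with 2 arrays each. The 75th percentile of the signal ranged from 67.6 to 450 units and the share of spots well above background from 41.8% to 59.4%. Replicate 2 of the ovarian CD4 cells and replicate 2 of the allogeneic splenic CD4 cells were the dimmest, with 75th percentiles of 68.2 and 67.6. Arrays of 1 group correlated with Pearson r between 0.938 and 0.996 across genes, which are not independent replicates. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate animals, so the p-values measure only the spread between these samples. Tests covered 22831 features, of which 13696 carry a gene symbol and the others are unnamed probes. A difference is given on the log2 scale ± its standard error from a limma fit shared by all 16 arrays. A gene is said to have risen, fallen or changed only where its Benjamini-Hochberg adjusted p was under 0.05. A list is said to have risen or fallen where camera called it as a whole. This can happen with 0 of its genes called, and such genes are not said to have changed. "At least N-fold" stands for a gene that was not well above background on any array of the lower group: the mean of the higher group is then set against the lowest signal called well above background. A fold without 1 array beside such a bound is the fitted difference from signals below background. It is not itself a bound, and a bound could only be equal or smaller. Where the lower group was above background on only 1 array the size is uncertain, as for Tigit, Gp2 and Ccl17 in CD8 cells, Bace2 and Zbtb16 in the CD4 transplant comparison and Cd8b1 between ovarian subsets.

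Ovarian CD8 cells (n = 4) were compared with splenic CD8 cells of allogeneic recipients (n = 3) to ask how donor T cells in the target organ differ from those in a lymphoid organ. Some genes of naive and memory states and single chemokine receptors were lower in the ovary. Cxcr4, the receptor for the retention chemokine CXCL12, changed by -1.69 ± 0.18 (adjusted p = 0.00102). Tcf7, a transcription factor of naive and memory T cells, changed by -0.99 ± 0.12, Dapl1, a gene of the same states, by -1.74 ± 0.19, and Ccr6, a chemokine receptor, by -2.22 ± 0.27. Il7r, the receptor for a survival cytokine, changed by -1.21 ± 0.22 (adjusted p = 0.0323). Genes of sterol synthesis were higher in the ovary, where the enzymes Sqle and Idi1 rose by 1.33 ± 0.19 and 0.94 ± 0.15. The enzymes of steroid hormone synthesis Hsd3b1 and Cyp11a1 were at least 19.7-fold and at least 3.85-fold higher (adjusted p = 0.000183 and 0.0138). Il13, a type 2 cytokine, was at least 4.08-fold higher, Ccl17, a chemokine that attracts CCR4-bearing cells, rose by 4.13 ± 0.36, and Lta, lymphotoxin alpha, rose by 1.02 ± 0.11. Skil, a repressor of TGF-beta signalling, rose by 1.08 ± 0.11, and Cdh1, which encodes the adhesion molecule E-cadherin, by 3.77 ± 0.61. Me1, malic enzyme, was at least 14.3-fold higher. Aldh1a1, a retinal dehydrogenase, rose by 3.64 ± 0.46. Wt1, a transcription factor of gonadal somatic cells, was called higher, but no size is given because it was well above background on only 2 of the 4 ovarian arrays and on 0 splenic arrays. Fcmr, the IgM receptor of B cells, was at least 5.62-fold lower, and Fcrla, a B-cell gene, at least 2.79-fold lower. Cd5l, a macrophage-secreted protein, was at least 19.7-fold lower (fitted difference down to 17.6-fold without 1 array). Mgp, a stromal matrix protein, was at least 5.03-fold higher, and Apoe, an apolipoprotein of macrophages, and Fdps, a sterol synthesis enzyme, rose by 1.76 ± 0.34 and 0.96 ± 0.18. H2-Aa, a class II histocompatibility gene, changed by -1.99 ± 0.39.

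Of the T-cell genes whose values were to be given in any case, Tcf7 and Il7r were among those that fell between spleen and ovary in CD8 cells, and 19 were not called. The killing genes differed by -1.30 ± 0.67 (Gzma), -0.39 ± 0.41 (Gzmb), -0.66 ± 0.14 (Prf1) and 0.28 ± 0.31 (Fasl), and Ifng by 0.36 ± 0.51. Receptors of migration differed by 0.32 ± 0.27 (Cxcr3), 0.71 ± 0.18 (Cxcr6), -0.61 ± 0.57 (Cd69), -0.71 ± 0.21 (Ccr7) and -0.43 ± 0.24 (S1pr1), and their regulator Klf2 by -0.69 ± 0.20. Inhibitory receptors differed by 0.25 ± 0.27 (Pdcd1), -0.04 ± 0.50 (Havcr2) and 0.62 ± 0.51 (Lag3). The remaining values were -1.20 ± 0.34 for Foxp3, 0.31 ± 0.33 for Il2ra, -0.08 ± 0.21 for Mki67, 0.23 ± 0.31 for Tbx21 and -0.11 ± 0.19 for Eomes. Prf1 (adjusted p = 0.0703) was called with 6 other settings, the slide as a block among them, and Cxcr6, Ccr7, S1pr1, Klf2, Foxp3 and Gzma with estimated array weights.

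Gene lists fixed before the data were examined were tested in the same comparison with camera, which sets a list against all other genes. Naive and memory genes fell in ovarian CD8 cells: of 24 measured, 5 fell and 19 were not called (9 fell and 2 rose adjusted over the list alone; adjusted p = 3.31e-09). Lymphoid homing genes fell as a list, with 1 of 15 called (5 adjusted over the list alone; adjusted p = 4.56e-05). Cholesterol synthesis genes rose, 5 of 21 being called and 16 not (7 adjusted over the list alone; adjusted p = 2.22e-08). Tissue residency genes rose, with Skil and Cdh1 called of 21 (9 adjusted over the list alone; adjusted p = 2.91e-07). Theca and luteal genes rose, with Hsd3b1 and Cyp11a1 called of 11 (2 adjusted over the list alone; adjusted p = 8.35e-05), as did granulosa genes, with Wt1 called of 12 (2 adjusted over the list alone; adjusted p = 0.00384). Stromal genes rose with 1 of 10 called (1 adjusted over the list alone; adjusted p = 0.0175) and macrophage genes with 1 of 19 (3 adjusted over the list alone; adjusted p = 0.00195). B-cell genes fell with 1 of 14 called (8 adjusted over the list alone; adjusted p = 2.45e-08), dendritic-cell genes with 1 of 14 (7 adjusted over the list alone; adjusted p = 2.29e-06) and erythroid and platelet genes with 0 of 11 (3 adjusted over the list alone; adjusted p = 6.1e-06). In 4 further lists no member was called on either adjustment: cell cycle (35 genes, lower, adjusted p = 0.000334), ribosomal proteins (34, higher, adjusted p = 0.0336), endothelium (9, lower, adjusted p = 0.0349) and pan T cell (18, higher, adjusted p = 0.0365). None of these 15 calls was kept with an estimated correlation, where the lists had adjusted p = 0.143 to 0.814 with an estimated correlation. Cytotoxic effector genes (17 measured, 0 called), inhibitory receptors (19, 0 called) and the interferon gamma response (24, 0 called) were not called as lists (adjusted p = 0.716, 0.91 and 0.91), nor were inflammatory chemokine receptors, with 2 of 12 lower (adjusted p = 0.841). The ribosomal, endothelial and pan T cell lists also lost their calls with quantile normalization and with normexp. With the slide as a block the ribosomal list lost its call too.

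In all, 123 features differed between ovarian and splenic CD8 cells, 61 higher and 62 lower in the ovary, and 97 of them carry a symbol. All 123 had the arrays of both tissues fully separated, as did 12.7% of all features, against 5.71% by chance. With the slide as a block 199 features differed. On slide 1 alone (2 ovarian and 2 splenic arrays) 255 differed, 64 higher and 191 lower, and on slide 2 alone (2 ovarian arrays and 1 splenic) 0 did. Leaving out ovarian replicate 1, 2, 3 or 4 gave 65, 49, 262 or 52 features, and leaving out splenic replicate 1, 2 or 3 gave 55, 67 or 217. The balance of directions also moved, to 84 higher and 178 lower without ovarian replicate 3. The calls of Apoe and H2-Aa ended without any 1 of the 7 arrays (adjusted p up to 0.147 and 0.165), and that of Fdps without any except ovarian replicate 3 (up to 0.145). Fcrla and Cd5l, with adjusted p up to 0.0926 and 0.148, and Il7r and Cdh1 lost their calls without ovarian replicate 1, 2 or 4 or splenic replicate 1 or 2 (up to 0.173 for Il7r and 0.0843 for Cdh1). Those of Cyp11a1 and Mgp ended without ovarian replicate 2 or 4 or splenic replicate 1 or 2 (adjusted p up to 0.0814 and 0.157), and that of Idi1 without replicate 1 or 2 of either tissue (adjusted p up to 0.0843). Sqle lost its call on each slide alone and with the replicate block (adjusted p up to 0.596). The calls of Cyp11a1, Il13, Wt1, Fcmr, Fcrla, Cd5l, Mgp and Apoe also ended with normexp background correction and with a common signal floor.

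**Figure D1:**
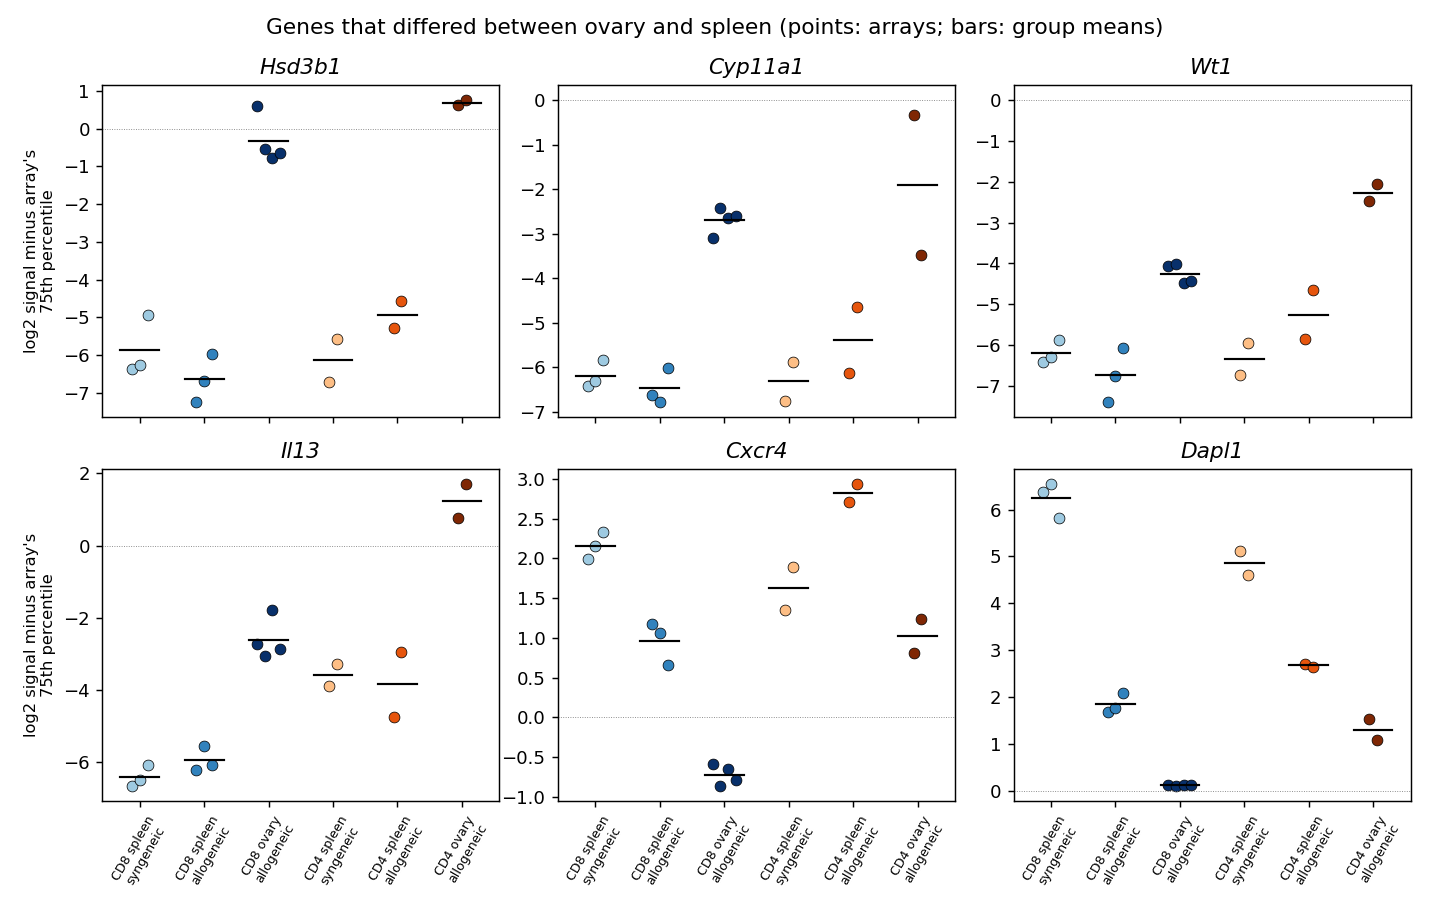
Signals of 6 genes that differed between ovary and spleen, as log2 signal minus the array's 75th percentile, in the 6 groups. Points are single arrays and bars are group means. Hsd3b1 lay between -0.77 and 0.76 on the 6 ovarian arrays and at or below -4.58 on the 10 splenic arrays.

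Ovarian CD4 cells (n = 2) were set against splenic CD4 cells of allogeneic recipients (n = 2) with the same question. Il7r changed by -1.93 ± 0.29 (adjusted p = 0.0138), Cxcr4 by -1.80 ± 0.24 (adjusted p = 0.00847) and Tcf7 by -0.92 ± 0.15 (adjusted p = 0.0208). The monocyte-attracting chemokine Ccl7 was at least 34.5-fold higher in the ovary. Il13 and Hsd3b1 were at least 22.1-fold and at least 15.1-fold higher (adjusted p = 0.00367 for both). Without 1 array the fitted difference of Il13 was as small as 18.1-fold. The sterol gene Sqle rose by 1.38 ± 0.25. Wt1 was at least 1.94-fold higher. The B-cell gene Fcmr was at least 7.76-fold lower in the ovary, and Cd79b, a chain of the B-cell receptor, and Cd5l changed by -1.96 ± 0.36 and -5.23 ± 1.08 (Cd5l -6.90 to -3.56 without 1 array). Trem2, a macrophage receptor, was at least 20.8-fold higher, but its fitted difference without 1 array was as small as 9.78-fold. Nr5a2, a regulator of steroid synthesis, changed by 2.99 ± 0.50, and Me1 was at least 5.94-fold higher. Other changes were in Idi1 (1.15 ± 0.20), Lta (0.86 ± 0.15), Dapl1 (-1.37 ± 0.25) and the ATP receptor P2rx7 (2.22 ± 0.47, or 1.38 to 3.05 without 1 array). Qpct, which modifies chemokines, was at least 2.38-fold higher, and the lymphocyte protease Ctsw rose by 1.40 ± 0.26. The mitotic genes Ccnb2 and Birc5 rose by 0.99 ± 0.20 and 1.68 ± 0.34 (Birc5 on 1 ovarian array, since the other spot was an outlier).

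Tcf7 and Il7r were also among those that fell between spleen and ovary in CD4 cells, where 19 of the T-cell genes were not called. Killing genes differed by 0.66 ± 0.88 (Gzma), 0.40 ± 0.48 (Gzmb), -0.46 ± 0.19 (Prf1) and 0.37 ± 0.40 (Fasl), and Ifng by 0.47 ± 0.67. Migration genes differed by 0.13 ± 0.35 (Cxcr3), 0.75 ± 0.24 (Cxcr6), 0.02 ± 0.75 (Cd69), -1.08 ± 0.27 (Ccr7), -0.72 ± 0.32 (S1pr1) and -0.69 ± 0.26 (Klf2). Inhibitory receptors differed by 0.20 ± 0.35 (Pdcd1), 0.25 ± 0.66 (Havcr2) and 0.20 ± 0.66 (Lag3). The others were -0.09 ± 0.45 for Foxp3, 0.12 ± 0.43 for Il2ra, 0.36 ± 0.27 for Mki67, 0.71 ± 0.41 for Tbx21 and -0.50 ± 0.25 for Eomes. Ccr7 was called without ovarian replicate 1 (adjusted p = 0.00805) and with normexp background correction, and S1pr1 on slide 1 alone.

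Among the fixed lists, cell cycle genes rose in ovarian CD4 cells, with 2 of 35 called (16 adjusted over the list alone; adjusted p = 3.17e-10). Cholesterol synthesis rose with 4 of 21 called (8 adjusted over the list alone; adjusted p = 2.09e-08), granulosa genes with 2 of 12 (3 rose and 1 fell adjusted over the list alone; adjusted p = 2.32e-05) and theca and luteal genes with Hsd3b1 called of 11 (3 adjusted over the list alone; adjusted p = 0.00314). Glycolysis rose with 0 of 21 called (3 adjusted over the list alone; adjusted p = 2.24e-05), chemokines of T cells with 0 of 8 (3 adjusted over the list alone; adjusted p = 0.0164), and tissue residency with 2 of 21 (5 adjusted over the list alone; adjusted p = 0.00314). T-cell cytokines rose with 2 of 18 called (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0425), oxidative phosphorylation with 0 of 38 on either adjustment (adjusted p = 0.00314), and immediate early and stress genes with 0 of 25 (2 adjusted over the list alone; adjusted p = 0.0179). B-cell genes fell with 4 of 14 called (9 fell and 1 rose adjusted over the list alone; adjusted p = 2.4e-07), naive and memory genes with 4 of 24 (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.000764), lymphoid homing genes with 1 of 15 (3 fell and 1 rose adjusted over the list alone; adjusted p = 0.0115) and erythroid and platelet genes with 0 of 11 (1 fell and 1 rose adjusted over the list alone; adjusted p = 0.0171). All 14 calls ended with an estimated correlation: the lists then had adjusted p = 0.158 to 0.629 with an estimated correlation.

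In this CD4 comparison 207 features differed, 90 higher and 117 lower in the ovary, all with separated arrays (33.7% of all features, against 33.3% by chance). The balance of directions was not stable: 137 were higher and 83 lower without splenic replicate 1, 49 and 164 without ovarian replicate 2, 1099 and 788 without splenic replicate 2, and 185 and 341 with normexp. With the slide as a block the count was 415, on slide 1 alone (1 array against 1, with the spread of the other groups) 2076, and on slide 2 alone 0. It was 323 without ovarian replicate 1 and 1887 without splenic replicate 2. Lists called numbered 6 without splenic replicate 1, 8 without ovarian replicate 2 and 9 without splenic replicate 2. The call of Tcf7 ended without ovarian replicate 2 (adjusted p = 0.0734) and that of Sqle without either ovarian replicate (up to 0.0818). Dapl1, Trem2 and Cd79b lost theirs without splenic replicate 1 or ovarian replicate 2 (up to 0.132, 0.089 and 0.109), Nr5a2 and Cd5l without replicate 1 of either tissue (up to 0.0655 and 0.133), and P2rx7 and Qpct without any array except splenic replicate 2 (up to 0.134 and 0.117). A single array ended the calls of Ctsw and Lta (ovarian replicate 1, 0.0925 and 0.0697), Ccnb2 and Idi1 (ovarian replicate 2, 0.182 and 0.0815), and Birc5 and Me1 (splenic replicate 1, 0.0624 and 0.0677). When only these 4 arrays were fitted, 0 features were called, as also with estimated array weights, so every CD4 gene named here was called only with the spread shared over the 6 groups.

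The ovarian calls of both subsets overlapped. Of the genes higher in the ovary 18 were called in both subsets (0.24 for independent lists, Fisher's exact test p = 9.92e-30), among them Hsd3b1, Me1, Il13, Sqle and Wt1. Of those lower 17 were shared (0.318 for independent lists, Fisher's exact test p = 2.11e-25), among them Tcf7, Il7r, Cxcr4 and Fcmr, and 0 were called in opposite directions, either way. Genes are not independent replicates, and both comparisons share the estimate of each gene's spread, so these p-values are too small. For the opposite directions independent lists would share 0.313 and 0.244 genes, so the count of 0 carries little weight. Among the shared lower genes, the B-cell gene Fcmr was above background on every allogeneic splenic array and on 0 ovarian arrays. The B-cell list also fell in both comparisons. Which cells of the sorts made the transcripts that fell in the ovary was not tested. The 35 shared genes became 60 with the slide as a block. They numbered 19, 12, 61 and 14 without ovarian CD8 replicate 1, 2, 3 and 4, 21 and 23 without splenic CD8 replicate 1 and 2, and 53 without allogeneic splenic CD4 replicate 2. The difference between subsets was tested directly as an interaction of tissue and subset, for which limma called 0 features, with 2539 at an unadjusted p under 0.05. Other settings called 38 with quantile normalization, 56 with normexp, 6 with the slide as a block, 1542 on slide 1 alone and 0 on slide 2 alone. Without single arrays the interaction count was 66 (ovarian CD4 replicate 1), 103 (ovarian CD4 replicate 2), 40 and 1381 (splenic CD4 replicates 1 and 2), 4 (ovarian CD8 replicate 3) and 57 (splenic CD8 replicate 3).

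Splenic CD8 cells of allogeneic recipients (n = 3) were compared with those of syngeneic recipients (n = 3), the control without an alloresponse. Genes of killing rose with the allogeneic transplant: Gzmb, granzyme B, by 7.41 ± 0.43 (170-fold, on 2 allogeneic arrays, since 1 spot was an outlier), Gzma by 6.12 ± 0.72, Fasl by 4.92 ± 0.33, Ifng by 3.75 ± 0.54 and Prf1, perforin, by 2.05 ± 0.15. Inhibitory receptors rose: Pdcd1, which encodes PD-1, by 6.18 ± 0.29 (72.5-fold, adjusted p = 2.2e-08), Tigit by 6.56 ± 0.18, Lag3 by 5.59 ± 0.54, Havcr2, TIM-3, by 3.01 ± 0.54, and Tox, a transcription factor of chronically stimulated cells, by 3.27 ± 0.18. Proliferation genes rose, with Mki67 at 3.84 ± 0.22, Cdk1 at 4.38 ± 0.21, Ccnb2 at 4.46 ± 0.16 and Ube2c at 4.81 ± 0.20, together with the cycle inhibitor Cdkn2a at 7.15 ± 0.25. Il21 and Il10 were at least 37.5-fold and at least 13.7-fold higher, and the chemokines Ccl3 and Ccl4 rose by 5.84 ± 0.40 and 4.59 ± 0.53. Tff1, a trefoil peptide of mucosal surfaces, had the largest rise among the symbols that met the naming rule, at least 1207-fold. Naive-cell genes fell: Ccr7, the receptor that guides T cells into lymph nodes, changed by -4.41 ± 0.22, Dapl1 by -4.40 ± 0.21, Tcf7 by -2.20 ± 0.12, Il7r by -1.99 ± 0.24, S1pr1, the egress receptor, by -1.74 ± 0.26 and Klf2 by -1.18 ± 0.21. Scg5, a chaperone of secretory granules, changed by -6.55 ± 0.17, Gp2, a mucosal receptor for bacteria, by -7.80 ± 0.74 and Il6ra, the interleukin 6 receptor, by -5.68 ± 0.73 (-6.40 to -4.51 without 1 array), without a call on slide 1 alone. Tmprss6 was at least 115-fold higher.

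Of the T-cell genes to be given in any case 15 rose, Cd69 (-0.65 ± 0.61) was not called, and Ccr7, Tcf7, Il7r, S1pr1 and Klf2 were among those that fell. Risers not given above were Cxcr6 (2.67 ± 0.20), Cxcr3 (1.85 ± 0.28), Il2ra (3.79 ± 0.35), Foxp3 (2.20 ± 0.36), Tbx21 (2.95 ± 0.33) and Eomes (1.80 ± 0.20). The effector regulators Prdm1 and Il12rb1 rose by 4.39 ± 0.25 and 3.33 ± 0.17, the helper-cell regulators Ikzf2 and Rora by 3.76 ± 0.29 and 3.20 ± 0.29, and Ccr6 by 2.94 ± 0.29. Cd8a differed by 0.54 ± 0.40 and Cd3e by 0.27 ± 0.18, neither called, while Cd8b1 changed by -0.79 ± 0.25 (adjusted p = 0.0239) and Cd4 by -0.55 ± 0.18 (adjusted p = 0.0308). Cd8b1 lost its call without syngeneic replicate 1 or 2 or allogeneic replicate 3 (adjusted p up to 0.0814) and with quantile normalization or no filter on dim probes. Cd4 lost it without allogeneic replicate 1 or 2 or syngeneic replicate 2 or 3 (adjusted p up to 0.13) and with normexp, with no filter, on slide 1 alone and with only these 6 arrays fitted. Cd8a was called with the mean of a gene's probes (0.87), with only these 6 arrays fitted and with a common signal floor (0.54 in both). With quantile normalization and normexp, Cd3e was called higher (0.56 and 0.55). Another scaling moved the median of all features, which was -0.16 here, -0.08 with quantile normalization and -0.05 with normexp.

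In allogeneic CD8 cells 33 of 35 cell cycle genes rose and 2 were not called (33 adjusted over the list alone; adjusted p = 3.34e-22). Inhibitory receptors rose in 15 of 19 (15 adjusted over the list alone; adjusted p = 3.72e-11), and 19 of 24 naive and memory genes fell (19 adjusted over the list alone; adjusted p = 5.75e-11). Cytotoxic effector genes had 14 of 17 higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 4.97e-07), type 1 helper and effector transcription factors 10 of 15 higher (10 higher and 1 lower adjusted over the list alone; adjusted p = 5.74e-05), regulatory T-cell genes 9 of 15 higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.000144), and type 2 and type 17 helper genes 7 of 12 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.00075). These 7 lists kept their calls with an estimated correlation. Ribosomal protein genes such as Rps19 (-1.08 ± 0.12) fell in 24 of 34 (28 fell and 1 rose adjusted over the list alone; adjusted p = 1.16e-06). Oxidative phosphorylation genes such as Cycs (0.94 ± 0.14) rose in 15 of 38 (15 adjusted over the list alone; adjusted p = 1.19e-05), and glycolysis genes such as Gapdh (1.44 ± 0.13) in 13 of 21 with 2 lower (13 and 2 adjusted over the list alone; adjusted p = 0.000417). Type I interferon response genes such as Oas1a (3.33 ± 0.22) rose in 12 of 28 with 1 lower (13 and 1 adjusted over the list alone; adjusted p = 0.000202), and costimulation genes in 12 of 18 with 1 lower (12 and 1 adjusted over the list alone; adjusted p = 1.19e-05). Chemokines rose in 5 of 8 with 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.00152) and chemokine receptors in 7 of 12 with 3 lower (7 and 3 adjusted over the list alone; adjusted p = 0.0143). B-cell genes such as Cd79b (-2.17 ± 0.29) fell in 11 of 14 (11 adjusted over the list alone; adjusted p = 0.000379) and dendritic-cell genes in 7 of 14 (8 fell and 1 rose adjusted over the list alone; adjusted p = 0.0303). These 9 lists had adjusted p = 0.0541 to 0.586 with an estimated correlation. The ribosomal list also lost its call with quantile normalization and with normexp. The dendritic-cell list kept its call in only 11 of 18 settings, losing it with the slide as a block among others.

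Between allogeneic and syngeneic CD8 cells 8773 features differed, 4291 higher and 4482 lower in allogeneic cells. For 16 of these neither group was well above background. The arrays were fully separated for 8459 of the 8773 (53.5% of all features, against 10% by chance). With the slide as a block the count was 9642, within slide 1 it was 8999 and within slide 2 it was 1901, 1221 higher and 680 lower. The slide 2 fit did not call Cxcr3, Foxp3, Havcr2, Tbx21, Klf2, S1pr1, Ccr6, Rps19, Cycs, Cd4 or Cd8b1. Leaving out 1 array gave 6887 to 9646.

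**Figure D2:**
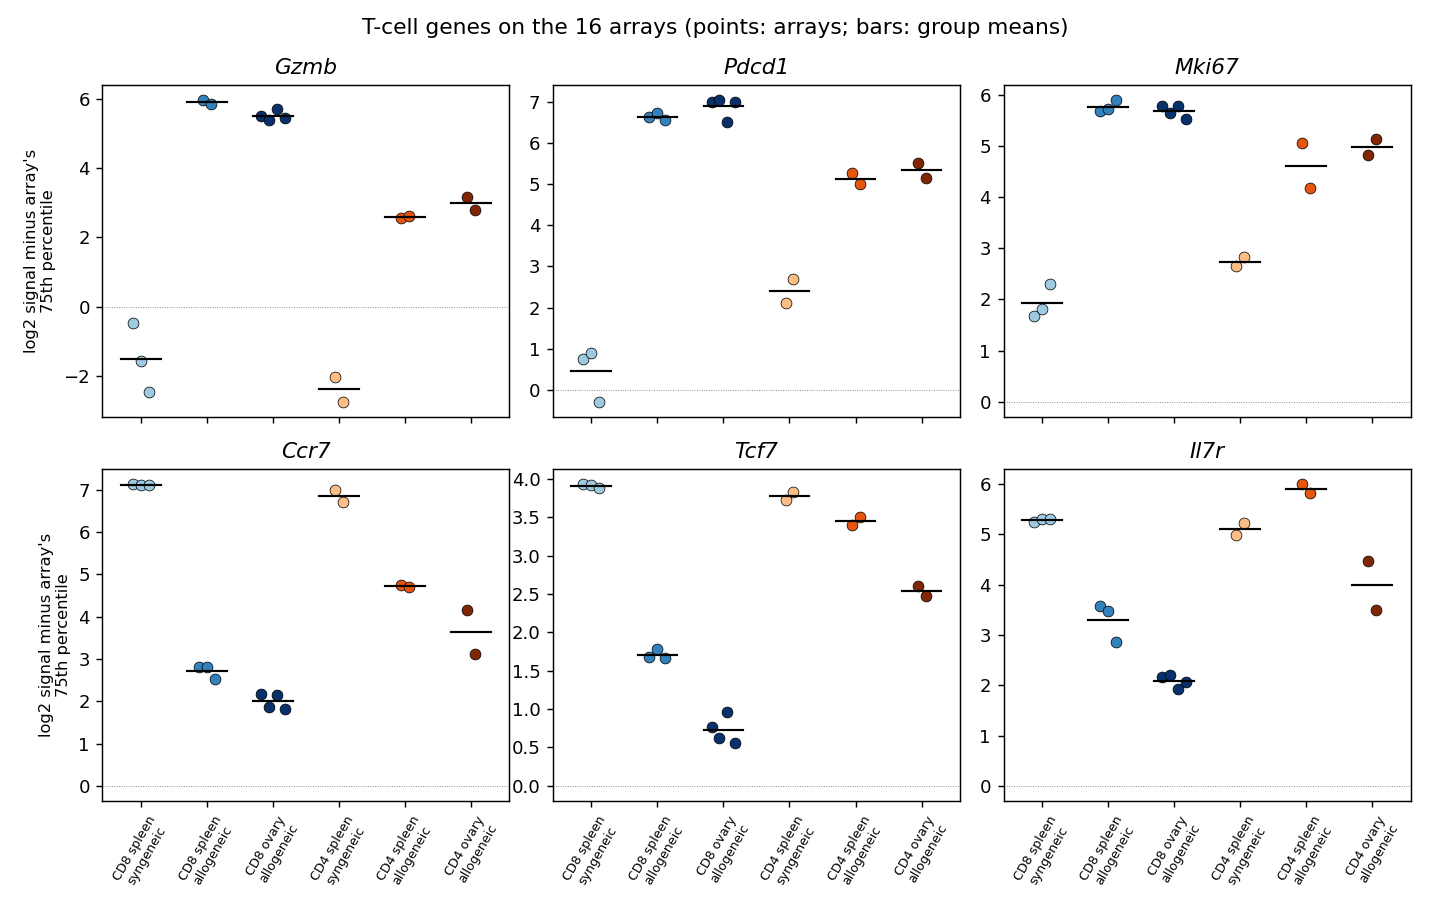
Signals of 6 T-cell genes in the 6 groups, as log2 signal minus the array's 75th percentile. Points are single arrays, 1 outlier spot of Gzmb being left out, and bars are group means. Mki67 lay between 4.17 and 5.90 on the 11 allogeneic arrays and between 1.67 and 2.82 on the 5 syngeneic arrays.

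Splenic CD4 cells were compared in the same way (n = 2 and n = 2). Gzmb rose by 4.98 ± 0.48 (31.6-fold, adjusted p = 8.93e-05), and the inhibitory receptors Pdcd1, Tigit and Lilrb4a by 2.73 ± 0.35, 4.00 ± 0.22 and 5.80 ± 0.51. Eomes, a T-box transcription factor of effector cells, rose by 3.11 ± 0.25, and Il18r1 and Prdm1 by 2.37 ± 0.30 and 2.32 ± 0.30. Il21, a helper cytokine, rose by 3.27 ± 0.49, Ccl3 and Ccl4 by 4.22 ± 0.49 and 4.22 ± 0.65 (Ccl4 2.94 to 5.49 without 1 array), and Cxcl9, a target of interferon gamma, by 3.85 ± 0.57. Bace2, a membrane protease, rose by 7.91 ± 0.62, Il10 by 3.07 ± 0.62, and Gcg, the glucagon precursor, was at least 80.1-fold higher. Ccr7 changed by -2.14 ± 0.27, Dapl1 by -2.18 ± 0.25 and Bach2, a repressor of effector differentiation, by -3.12 ± 0.40. Zbtb16, the transcription factor PLZF of natural killer T cells, changed by -5.78 ± 0.49 (adjusted p = 2.84e-05), and the chemokine receptor Ccr10 and the kallikrein Klk1b5 were at least 12-fold and at least 70.7-fold lower. Sqle changed by -1.69 ± 0.25. Cd8b1 changed by -1.80 ± 0.30. Macrophage genes also rose as a list in this comparison, and which cells made Cxcl9 was not tested.

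In CD4 cells 9 of these T-cell genes rose with the allogeneic transplant, 11 were not called, and Ccr7 was among those that fell. Risers besides Gzmb, Pdcd1 and Eomes were Lag3 (3.28 ± 0.66), Havcr2 (2.31 ± 0.66), Ifng (2.11 ± 0.67, adjusted p = 0.05 after rounding), Cxcr3 (1.91 ± 0.35), Mki67 (1.88 ± 0.27) and Cxcr6 (1.03 ± 0.24). Not called were Gzma (0.85 ± 0.88), Prf1 (0.00 ± 0.19), Fasl (0.56 ± 0.40), Cd69 (0.32 ± 0.75), S1pr1 (-0.45 ± 0.32), Klf2 (-0.54 ± 0.26), Tcf7 (-0.32 ± 0.15), Il7r (0.80 ± 0.29), Foxp3 (1.03 ± 0.45), Il2ra (0.01 ± 0.43) and Tbx21 (1.29 ± 0.41, adjusted p = 0.0502). Without 1 array the difference ran from 1.1 to 3.51 for Havcr2 and from 2.13 to 4.43 for Lag3. Havcr2 and Ifng lost their calls without either allogeneic replicate or syngeneic replicate 1 (adjusted p up to 0.307 and 0.328). Cxcr6 lost it without allogeneic replicate 1 or either syngeneic replicate (up to 0.0726), Lag3 and Il10 without syngeneic replicate 1 (0.062 and 0.0727), and Klk1b5 without syngeneic replicate 2 (0.0514). Without allogeneic replicate 2, Gzma, Fasl and Tbx21 were called (adjusted p = 0.0453, 0.0399 and 0.0415). Tbx21 was called with 8 other settings, the slide as a block among them, Il7r with the slide as a block, and Gzma, Fasl and Il7r on slide 1 alone. Foxp3 was called with normexp, and Tcf7 with the mean of a gene's probes.

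As a list, type 1 helper and effector transcription factors rose in allogeneic CD4 cells, with 10 of 15 called (12 adjusted over the list alone; adjusted p = 1.97e-07), and kept the call with an estimated correlation (adjusted p = 0.00826). Naive and memory genes fell in 14 of 24 with 1 higher (18 and 2 adjusted over the list alone; adjusted p = 1.78e-10). Cell cycle genes such as Cdk1 (2.74 ± 0.26) and Ccnb2 (1.52 ± 0.20) rose in 20 of 35 (20 rose and 1 fell adjusted over the list alone; adjusted p = 1.17e-08). Inhibitory receptors rose in 12 of 19 with 1 lower (15 and 1 adjusted over the list alone; adjusted p = 3.32e-07), cytotoxic effector genes in 8 of 17 (9 adjusted over the list alone; adjusted p = 2.9e-05) and type I interferon genes such as Oas1a (2.35 ± 0.27) in 12 of 28 (15 adjusted over the list alone; adjusted p = 8.04e-06). Cholesterol synthesis genes fell in 10 of 21 (11 adjusted over the list alone; adjusted p = 1.58e-06) and B-cell genes such as Cd79b (-2.31 ± 0.35) in 9 of 14 (9 adjusted over the list alone; adjusted p = 1.97e-07). The interferon gamma response rose in 7 of 24 with 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0054), and macrophage genes such as C1qb (1.89 ± 0.36) in 3 of 19 (3 adjusted over the list alone; adjusted p = 0.0021). Also called were costimulation (7 of 18 higher, 1 lower, 9 and 1 adjusted over the list alone, adjusted p = 0.00376), chemokines (4 of 8 higher, 5 adjusted over the list alone, adjusted p = 0.00376), chemokine receptors (6 of 12 higher, 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.0254), regulatory T-cell genes (5 of 15 higher, 6 and 1 lower adjusted over the list alone, adjusted p = 0.0409) and glycolysis (4 of 21 higher, 2 lower, 8 and 2 adjusted over the list alone, adjusted p = 0.0487). Dendritic-cell genes fell in 4 of 14 (5 adjusted over the list alone; adjusted p = 0.00376) and the hypoxia response in 4 of 17 (4 adjusted over the list alone; adjusted p = 0.0247). Apart from the first, the 17 lists had adjusted p = 0.0923 to 0.679 with an estimated correlation. The regulatory T-cell list kept its call in only 7 of 16 settings, losing it with quantile normalization, on each slide alone and without 3 of the 4 arrays. Glycolysis kept it in 8 of 16, losing it with the replicate block and the series matrix among others.

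Between allogeneic and syngeneic CD4 cells 3678 features differed, 2377 higher and 1301 lower in allogeneic cells, all with separated arrays (51.2% of all features, against 33.3% by chance). For 58 neither group was well above background. The count was 5031 with the slide as a block, 6308 on slide 1 alone, 0 on slide 2 alone and 1384 without syngeneic replicate 1. With only these 4 arrays fitted it was 7. That fit called, of the CD4 genes named for this comparison, Bace2 and Gcg.

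The transplant calls of both subsets shared 1313 higher genes (447 for independent lists) and 827 lower genes (255 for independent lists, Fisher's exact test p = 4.53e-283), and 43 were called higher in CD8 and lower in CD4 cells (245 for independent lists) and 138 lower in CD8 and higher in CD4 cells (467 for independent lists). Shared higher genes included Gzmb, Pdcd1, Tigit and Mki67, and shared lower genes included Ccr7 and Dapl1. These comparisons also share the estimate of each gene's spread, so the p-value of their overlap is too small. Without syngeneic CD4 replicate 1 the 2140 shared genes became 928. The interaction of transplant and subset called 2728 features, 1204 with the larger rise or smaller fall in CD8 cells and 1524 in CD4 cells. Zbtb16 had a difference of 8.61 ± 0.64 towards CD8 cells and Cxcl9 of -6.46 ± 0.74, towards CD4 cells. Tmem273 and Epdr1 were called towards CD8 cells and Mab21l3 and Gp2 towards CD4 cells, without a size because each was above background on no array of at least 1 of the 4 groups. Among the sort markers Cd4 (-0.87 ± 0.29), Cd8a (0.26 ± 0.64, on no CD4 array above background), Cd8b1 (1.01 ± 0.39) and Cd3e (-0.10 ± 0.28) were not called, Cd4 being called without allogeneic CD4 replicate 1 or allogeneic CD8 replicate 3, with the mean of a gene's probes and over probes above background on all 16 arrays (lowest adjusted p = 0.0269). The interaction count was 3786 with the slide as a block, 3960 on slide 1 alone and 0 on slide 2 alone. It was 1743, 1779 and 4230 without allogeneic CD8 replicate 1, 2 and 3, 1613 without syngeneic CD8 replicate 2, and 1326 and 1731 without syngeneic CD4 replicate 1 and 2. Of the 1326, 758 were towards CD8 and 568 towards CD4 cells, the reverse of the balance above.

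Ovarian CD8 cells (n = 4) were also compared with ovarian CD4 cells (n = 2), which checks the sort. Cd8a was at least 478-fold higher on the CD8 arrays and Cd8b1 rose by 8.08 ± 0.26, while Cd4 changed by -3.27 ± 0.19 and Cd3e differed by 0.29 ± 0.19 without a call. Cd4 was still well above background on all 4 ovarian CD8 arrays, and Cd8b1 on 2 of 2 allogeneic splenic CD4 arrays. The differences alone therefore do not show that the sorts were pure. Between ovary and spleen these 4 markers were not called in either subset (Cd3e in CD8 cells was called with array weights), with Cd8a at 0.16 ± 0.38, Cd8b1 at 0.04 ± 0.23, Cd4 at 0.31 ± 0.17 and Cd3e at 0.23 ± 0.17 in CD8 cells. Killing genes and some inhibitory receptors were higher in ovarian CD8 cells, with Prf1 at 3.25 ± 0.16, Gzma at 4.19 ± 0.76, Klrc1, an NKG2 receptor, 18.4-fold higher, Nkg7 at 1.62 ± 0.16, Eomes at 2.77 ± 0.21, Pdcd1 at 1.56 ± 0.30 and Havcr2 at 2.84 ± 0.57. Tmprss6, a membrane serine protease, and Nudt11, a phosphatase of inositol phosphates, were at least 47.1-fold and at least 17-fold higher, and Cd160, a receptor of cytotoxic cells, rose by 3.89 ± 0.41, Cycs by 0.63 ± 0.15 and Ccnb2 by 0.79 ± 0.17. Regulatory and helper genes were higher in ovarian CD4 cells, with Foxp3 at -4.52 ± 0.39, Lrrc32, a TGF-beta docking receptor, at -5.36 ± 0.42, Il13 at -3.85 ± 0.48 and Tnfsf11, RANK ligand, 18.4-fold lower in CD8 cells. Il4 and Ccr4 were at least 10.2-fold and at least 23.9-fold lower in CD8 cells. Tcf7 and Il7r differed by -1.81 ± 0.13 and -1.89 ± 0.25. Macrophage genes were also higher on the CD4 arrays, with Apoe at -3.85 ± 0.38, Lyz2 at -3.85 ± 0.44 and C1qb at -3.42 ± 0.31. Fn1, fibronectin, and Gcg were at least 79.1-fold and at least 119-fold lower on the CD8 arrays. Without 1 array the fitted Fn1 difference was as small as 34.1-fold, so a bound would be no larger. Its call ended on slide 1 alone.

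In this comparison 18 of 19 macrophage genes were lower in ovarian CD8 than CD4 cells (19 adjusted over the list alone; adjusted p = 9.62e-17). Regulatory T-cell genes were lower in 11 of 15 (12 adjusted over the list alone; adjusted p = 6.14e-10), T-cell cytokines in 10 of 18 (12 adjusted over the list alone; adjusted p = 5.57e-09) and type 2 and type 17 helper genes in 8 of 12 (10 adjusted over the list alone; adjusted p = 3.69e-08). Cytotoxic effector genes were higher in 12 of 17 and lower in 2 (13 and 2 adjusted over the list alone; adjusted p = 7.07e-07). The last 4 lists kept their calls with an estimated correlation. Cell cycle genes were higher in 17 of 35 (24 adjusted over the list alone; adjusted p = 1.54e-08), oxidative phosphorylation genes in 8 of 38 (16 adjusted over the list alone; adjusted p = 1.29e-06), natural killer cell genes in 6 of 10 with 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.027) and cholesterol synthesis genes in 5 of 21 (7 adjusted over the list alone; adjusted p = 0.0304). Endothelial genes were lower in 4 of 9 (5 adjusted over the list alone; adjusted p = 0.00743), naive and memory genes in 11 of 24 with 4 higher (12 and 5 adjusted over the list alone; adjusted p = 0.00927), dendritic-cell genes in 5 of 14 with 1 higher (6 and 1 adjusted over the list alone; adjusted p = 0.0134) and hypoxia genes in 5 of 17 with 1 higher (5 and 1 adjusted over the list alone; adjusted p = 0.0316). Apart from the 4 lists named, these had adjusted p = 0.0665 to 0.472 with an estimated correlation. Inhibitory receptors were not called as a list, with 7 of 19 higher and 3 lower (adjusted p = 0.114). Neutrophil and fatty acid lists were called in none of the 5 comparisons in which lists were tested. Oocyte genes were not tested as a list because 4 were measured. In 24 pairs of a list and a comparison the median, the mean and the test of a list differed in sign, and none of these lists was called.

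Between the ovarian subsets 3996 features differed, 1933 higher and 2063 lower in CD8 cells, and for 77 neither group was well above background. The count was 5742 with the slide as a block, 3152 on slide 1 alone and 27 on slide 2 alone. With no filter on dim probes 1011 were higher and 1883 lower. The count was 1504 without ovarian CD4 replicate 2 and 2538, 2487 and 2540 without ovarian CD8 replicate 1, 2 and 4. Gzma and Pdcd1 lost their calls without ovarian CD4 replicate 2 (adjusted p = 0.0556 and 0.0662), Ccnb2 without ovarian CD4 replicate 1 (0.0755) and Cycs without either CD4 replicate (up to 0.0716).

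**Figure D3:**
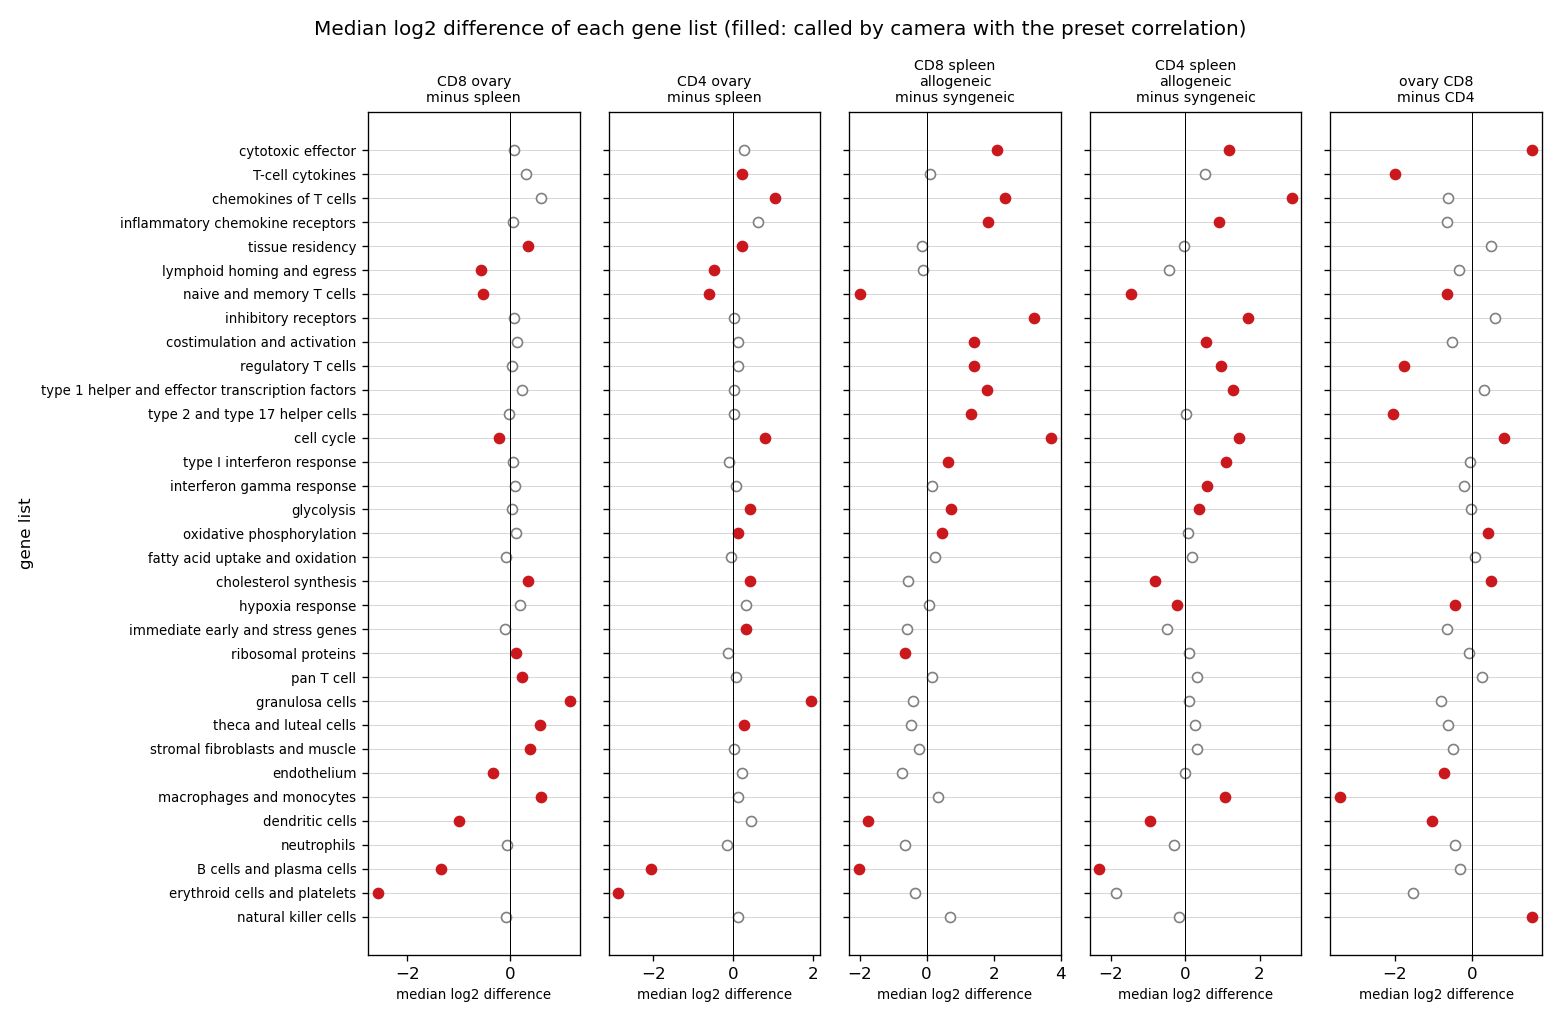
Median log2 difference of the measured genes of each of 33 lists in 5 comparisons. Filled circles are lists called by camera with the preset correlation, open circles are lists not called, and the cell cycle median was 3.72 between allogeneic and syngeneic CD8 cells.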

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

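Of the tests in this part, those of a spleen sample labelled as ovary were chosen after the distance of ovarian CD8 replicate 3 had been seen, and so were the splits kept within slides.

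In the 4 ovarian CD8 arrays, 101 genes were tested for an array far from the other 3 with Dixon's test, which picks out about 1 gene in 20 by chance. It picked out 18, of which 16 concerned replicate 3. Replicate 3 had Bace2 at -1.1 (others 0.08 to 0.21), Ccr6 at -0.15 (0.86 to 1.05), Cdh1 at -1.03 (-0.63 to -0.61), Ctsw at 5.85 (6.2 to 6.27), Cxcr6 at 8.02 (8.28 to 8.31), Fcrla at -4.59 (-7.07 to -6.66), Havcr2 at 4.19 (4.53 to 4.55) and Il21 at -0.22 (0.78 to 0.94). It also had Il6ra at 0.56 (-0.62 to -0.59), Lag3 at 3.28 (3.77 to 3.81), Lilrb4a at 5.66 (6.04 to 6.11), Nudt11 at 0.14 (1.05 to 1.16), P2rx7 at 2.12 (2.75 to 2.77), Pdcd1 at 6.51 (7 to 7.04), Prdm1 at 2.37 (3.04 to 3.11) and Tmem273 at 1.19 (2.24 to 2.29). Replicate 1 had Apoe at 1.19 (1.55 to 1.59) and Hsd3b1 at 0.61 (-0.77 to -0.55). Over all 22831 features replicate 3 was apart in 2612, against 286, 78 and 104 for replicates 1, 2 and 4.

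For replicate 3, a trend with signal brightness over all genes was argued against. With quantile normalization, which removes such a trend, 21 of the 101 genes had it apart, against 16 before. It does not remove an effect on particular genes that dim arrays share. Deviations of replicate 3 from its group mean correlated with those of slide 2 arrays of other groups at r = 0.223 to 0.559. The exception was syngeneic splenic CD8 replicate 2 (-0.083), the brightest of these. An effect shared by dim arrays stays open. A pure spleen sample labelled as ovary was also argued against: of the 8 probes well above background on the other 3 ovarian CD8 arrays, at least 4-fold over the lowest such signal, and on 0 of 10 splenic arrays, 7 (87.5%) were above background on this one, against at most 27.3% on a splenic array held out in turn. With dimmer probes let in it was 15 of 31, and 50 of 81 on splenic CD8 replicate 1 of the allogeneic recipients, so those decide nothing. Over the 262 genes called without it, its median position was 0.45 on a scale from the spleen mean (0) to the mean of the other ovarian arrays (1), with quartiles of -0.157 and 0.811, and 52.9% of genes lay nearer the spleen. These genes were chosen with the other ovarian arrays, which tends to put any array left out below 1. No such position is given for another ovarian replicate, so the value has no baseline and decides nothing. A mixture of cells from both organs stays open and was not tested, nor was any biological explanation.

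Chance could not be excluded for the CD8 ovary comparison: 2 of the 35 splits of its 7 arrays gave at least 123 features, the true split included. The other such split gave 211 and set replicate 3 of the ovary with the 3 splenic arrays, which points to a structure of the samples around that array. These splits ignore the slide; the 18 that keep the number of ovarian arrays on each slide include the same 2, and are too few for a share under 0.05. For the CD8 transplant comparison the 10 possible splits are too few for a share under 0.05; the true split gave 8773 and the highest other 0, and 1 of the 10 reached the true count.

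The effect of the allogeneic transplant differed between the subsets by a test of the interaction for 2728 features. Of 63 genes named in the transplant comparisons 33 were among them, 24 towards CD8 and 9 towards CD4. Many of the 63 were picked for large changes in these comparisons, so this share and balance are not those of all features. Of all 22831 features tested, 1204 were called towards CD8 and 1524 towards CD4 cells. Towards a subset means a larger rise or smaller fall there. Ccr7 and Dapl1, which fell more in CD8 cells, therefore count towards CD4. Towards CD8 cells were Gzma (5.27), Gzmb (2.43), Prf1 (2.05), Fasl (4.35), Cxcr6 (1.63), Pdcd1 (3.45), Il2ra (3.78), Mki67 (1.96), Ccnb2 (2.93), Ccr6 (3.17), Cdk1 (1.64), Cdkn2a (2.65), Cycs (0.76), Ikzf2 (2.63), Il12rb1 (1.79), Il21 (3.61), Prdm1 (2.08), Rora (1.76), Tff1 (3.95), Tigit (2.57), Tmprss6 (8.01), Tox (1.45), Ube2c (2.98) and Zbtb16 (8.61). Towards CD4 cells were Ccr7 (-2.27), Tcf7 (-1.88), Il7r (-2.78), Eomes (-1.31), Cxcl9 (-6.46), Dapl1 (-2.22), Gcg (-5.86), Gp2 (-6.79) and Scg5 (-2.32). The values of Il21, Tff1, Tmprss6, Gcg and Gp2 are not exact sizes, since each gene was above background on no array of at least 1 of the 4 groups.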

How the results depend on the processing

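Counts below move by more than a set margin from those given above; the cause of each move was not tested. The common floor, leaving out the 2 dimmest arrays, a filter on the groups compared, symbols only, and lists on single slides were added after results had been seen.

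Quantile normalization gave 336 features for CD4 ovary against spleen and 38 for tissue by subset (42.1% higher in CD8 cells), and normexp gave 526 and 56 (60.7%). Normexp also gave 22 lists for the ovarian subsets. Without a filter on dim probes the counts were 68 (CD8 ovary), 63 (CD4 ovary) and 1421 (transplant by subset). With probes above background on all 16 arrays they were 56 (CD8 ovary), 110 (CD4 ovary) and 4 (tissue by subset), and the mean of a gene's probes gave 4 for the last. A filter on the groups compared gave 9 for tissue by subset. With symbols only, the CD8 transplant comparison had 5660 and transplant by subset 1653. The main fit called 5520 and 1601 features with a symbol, so for such features these counts moved little. A 2-fold threshold left 4768 in the CD8 and 2436 in the CD4 transplant comparison, 1954 between ovarian subsets and 1414 shared transplant genes.

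With the slide as a block, counts were 199 (CD8 ovary), 415 (CD4 ovary), 6 (tissue by subset) and 60 shared ovarian genes. Slide 1 alone gave 255 for CD8 ovary, 2076 for CD4 ovary, 6308 for the CD4 transplant comparison, 1542 for tissue by subset and 8 lists for CD4 ovary. Slide 2 alone gave 0 for CD8 ovary, 0 for CD4 ovary, 1901 and 0 for the CD8 and CD4 transplant comparisons, 27 between ovarian subsets, 0 for transplant by subset and 8 lists for CD8 ovary. Single slides leave 1 or 2 arrays per group, and a lone array is assumed to vary like the other groups.

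With the replicate number as a block, counts were 75 (CD8 ovary), 106 (CD4 ovary), 1 (tissue by subset) and 17 shared ovarian genes. Whether equal numbers pair arrays was checked on residuals: r had a median of 0.145 over 33 pairs with the same number (-0.439 to 0.454) and -0.0809 over 72 with another, against 0.202 on the same slide and -0.201 on the other. Every replicate 1 array lies on slide 1 and every replicate 3 array on slide 2, and residuals of a group with 2 arrays mirror each other. The check therefore cannot separate pairing by number from the slide. The numbers were not treated as pairs in the main fit.

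Array weights gave 3686 for CD8 ovary, 0 for CD4 ovary, 13230 and 917 for the CD8 and CD4 transplant comparisons and 1327 for transplant by subset. Fitting only the groups compared gave 0 for CD4 ovary, 7 for the CD4 transplant comparison and 994 for transplant by subset. A common signal floor gave 639 for CD4 ovary and 232 for tissue by subset. Without the 2 dimmest arrays the counts were 196 (CD8 ovary), 1459 (CD4 ovary), 2485 (ovarian subsets), 1192 (tissue by subset) and 6 lists for CD4 ovary.

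Leaving out 1 array at a time gave 49 to 262 (CD8 ovary), 213 to 1887 (CD4 ovary), 6887 to 9646 and 1384 to 4355 (CD8 and CD4 transplant), 1504 to 3964 (ovarian subsets), 0 to 1381 (tissue by subset) and 1326 to 4230 (transplant by subset). Shared genes ranged from 12 to 61 (ovary) and from 928 to 2434 (transplant), and lists from 11 to 17 (CD8 ovary) and 6 to 13 (CD4 ovary).

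With a correlation estimated per list, lists called fell from 15 to 0 (CD8 ovary), 14 to 0 (CD4 ovary), 16 to 7 and 17 to 1 (CD8 and CD4 transplant) and 13 to 4 (ovarian subsets). The rotation test fry called 7 and 5 for the CD8 and CD4 ovary comparisons and 26 for the CD8 transplant comparison.

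For the 230 pairs of a gene and a comparison, 5141 values were recomputed: 4661 kept their call or lack of one, 434 lost a call, 46 gained one and 0 were called in the opposite direction. Lost calls numbered 119 on slide 2 alone, 58 with only the groups compared, 29 with array weights (8 gained), 25 without a filter, 22 on slide 1 alone (5 gained), 22 with the replicate block, 19 with normexp (5 gained), 15 with a common floor (2 gained), 9 without the 2 dimmest arrays (4 gained), 7 with quantile normalization (2 gained), 4 with the mean of probes (3 gained), 3 with the series matrix and 1 with all 16 arrays above background (2 gained). That last filter measured only 157 of the 230. The slide as a block gained 3, the trended variance 2, symbols only 2 and the filter on the groups compared 1, and none of these lost any.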

Other observations

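In this part the choice of the genes shared by both ovarian comparisons, the looser counts of ovarian markers and the test of brighter arrays were made after the results had been seen.

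Beyond the genes given above, those called in both the CD8 and the CD4 ovary comparison included Cish, a feedback inhibitor of cytokine signalling, higher by 1.22 ± 0.15 in CD8 and 0.98 ± 0.20 in CD4 cells. The monocyte attractants Ccl7 and Ccl12 were also called higher in both, without a size since neither was above background on any allogeneic splenic CD8 array. Lower in both were Tsc22d3, a glucocorticoid target (-1.43 ± 0.20 and -1.40 ± 0.26), and Pou2af1, a B-cell coactivator (-2.36 ± 0.41 and -3.46 ± 0.54).

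Transcripts of steroid synthesis were present on the ovarian arrays. A candidate source is RNA of ovarian cells in the sorted samples, in spite of the 2 rounds of sorting. Of 31 granulosa, theca and luteal markers, 2 (Cyp11a1 and Hsd3b1) were well above background on at least 5 of 6 ovarian arrays and at most 1 of 10 splenic arrays. The bound set beforehand, fewer than 3, was met, and would have counted against this source. That bound was set aside, a reading made after the values were seen. Of the markers, 17 were above background on more than 1 splenic array and could not meet the criterion. Star was among them (10 splenic and 5 ovarian arrays). Of the 14 able to meet it, only the same 2 did. By a looser count, not set beforehand, 8 of the 14 were found on at least 2 ovarian arrays. On none were 4 (Amh, Kitl, Lhcgr, Ptgfr), and 0 of the 31 markers had the opposite pattern. Oocyte, stromal and endothelial markers were not part of these counts, and single ones went both ways. Mgp and Col4a1 were above background on 4 and 3 ovarian arrays and on 0 splenic arrays. Oosp1 was so on 0 ovarian and 4 splenic arrays, and Esam on 1 and 6. RNA of ovarian cells and transcription by the T cells themselves cannot be told apart with these arrays. Brighter ovarian CD8 arrays were argued against, since spots well above background differed by -0.19 percentage points from the allogeneic splenic CD8 arrays.

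Macrophage genes were higher on ovarian CD4 than CD8 arrays. A raised signal floor of the dim CD4 arrays was argued against, since 19 of 19 markers were well above background on both ovarian CD4 arrays. RNA of macrophages or monocytes in the CD4 sorts may be a source, although the cells were sorted in 2 rounds: 19 of 19 markers were also higher on CD4 than CD8 arrays of the allogeneic spleen, and 17 of 19 in the syngeneic spleen. Median differences were 3.50 and 1.82 in the spleen and 3.42 in the ovary. The list was written before the data were examined, and its members with the strongest probe signals on the ovarian CD4 arrays were Itgam (6.17), Ctss (6.10) and Apoe (5.33), which lay at 5.49, 4.65 and 1.47 on the ovarian CD8 arrays; signals of different probes do not rank amounts of RNA. Whether T cells or other cells made these transcripts was not tested.

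The dim CD4 arrays might also raise the count of genes higher in allogeneic CD4 cells through a raised signal floor. The count did not fall, since 2419 were called with a common signal floor and 2377 without. This cannot exclude such a cause, because the same floor raised the counts of other comparisons.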
